A study of Caenorhabditis elegans with 4 samples.

How the data were processed

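RNA from dissected gonads of cde-1 mutant (allele tm1021) and wildtype (N2) C. elegans was compared on 4 Agilent arrays of 2 colours. Per the labels, 250 gonads were collected for a sample, total RNA was reverse transcribed with random primers, and each cDNA was divided and labelled with both Cy3 and Cy5. A young adult pair and an aged adult pair of mutant and wildtype RNA were each hybridised in both dye orientations. The 2 arrays of a stage therefore measured the same 2 cDNAs and were counted as 1 replicate, which left n = 2 over the 2 stages. Each stage and genotype had 1 RNA sample, so p-values measure the spread between 2 stages, which differ in age.

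The deposited table held 1 value per probe and array for 22562 probes. The submitters' processing notes name Agilent Feature Extraction and give no version; its dye normalization and background correction are not given in the sources used here. The deposited values were taken as the log10 ratio of the 2 channels, the convention of that program, and multiplied by 3.32 to give log2 ratios. The base was not checked against scanner signals. Were the deposited scale log2, every size would shrink by a factor of 3.32; the limma and camera tests and the correlations would stay the same, while each count or test that uses a fixed size in log2 units would change and was not rerun. The median of each deposited column was 0. A deposited ratio of exactly 0 made up 48.9% and 52.2% of the young adult columns and 45.0% and 43.7% of the aged adult columns, with the mutant in Cy5 given first. Such values were taken as spots without a ratio and left out. Signal over background was not used here, so the filter on dim spots is the one implied by these zeros.

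The direction of the deposited ratios was not stated. The 2 orientations of a stage correlated positively as deposited. Under the design fixed before the data were examined, this was read as 1 array of each pair having been turned before deposit, the values were averaged as they stood, and the direction was treated as unsettled. Had no array been turned, the average would hold the dye effect in place of the genotype effect; that reading was run as an alternative. The direction is called likely mutant over wildtype on the basis of number format alone. All 11541 and 12418 nonzero values of the arrays with the mutant in Cy5 were written in scientific notation, against 0 of the 10775 and 12704 values of the arrays with the mutant in Cy3, so these had been handled differently. If the latter were the ones turned, the former kept the program's ratio of Cy5 over Cy3, which is mutant over wildtype. The notation shows different handling and not the turn itself. Across genes, the orientation averages correlated negatively between the stages (Pearson -0.13) and the orientation differences positively (Pearson 0.25, Spearman 0.28). If a gene's dye effect is shared by the stages, the negative value goes against the reading that no array was turned. The positive value can arise either way, from shared dye effects if 1 array was turned or from a shared genotype effect if none was. The design treats the stages as near duplicates, and a genotype effect shared by them would go against a turned array. These values therefore do not settle the reading, nor which orientation was turned.

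Probes were named from the platform's annotation, with symbols updated through gene identifiers to the WBcel235 annotation. Of the 22562 probes, 7718 had 1 gene symbol, 0 had several and 14844 were unnamed here. The named probes covered 7477 genes; 6532 of these probes carried a sequence name and 7691 matched the reference. The build behind the array design is not given in the sources used here, so no coordinates are printed and the reference served for names, chromosomes and neighbours. On each array, a gene's value was the mean of its probes with a ratio there. A ratio was present for 8323 probes on all 4 arrays, 2310 of them named, and for 6042 on none. The 2222 genes with a value on all 4 arrays were tested, 28 of them with more than 1 probe.

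For each gene the orientations were averaged within a stage, and the 2 stage means were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05. Stage differences were not tested, and correlations between arrays or stages across genes carry no p-value because genes are not independent replicates. Only the correlation of neighbouring genes was set against shuffles, which treat genes as exchangeable. Of 20 gene lists fixed before the data were examined, 19 had no named probe, and the intracellular pathogen response list had 30 named members, of which 1 was tested. The 19 covered small RNA machinery, poly(U) and poly(A) polymerases, P granules, oocyte, sperm, proliferation, meiosis, kinetochore, histone, chromatin, apoptosis, folding stress and ribosomal genes, and markers of intestine, muscle, somatic gonad, hypodermis and neurons; no result was obtained for any of them. X-linked genes, planned as a list where chromosomes were known, were tested with camera at a preset correlation of 0.01. The position of a list's median was also given as its percentile among 10000 random lists of equal size.

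Genes were named by a rule set in advance. The rule takes cde-1, then the 12 genes with the highest and the 12 with the lowest mean ratio among those past the threshold with the same sign on all 4 arrays. Where fewer passed, the places were filled by genes of largest mean with the same sign on all 4 arrays, given as values that did not pass. It adds up to 4 members of each fixed list and the 10 largest stage differences whose 4 array values separated the stages. The probe for cde-1 was not among the named ones, so the mutated gene could not serve as a check of the labels.

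The gene test was run on simulated data of 2222 genes before use. It recovered 54 of 100 genes changed by 3 log2 units and 99 of 100 changed by 6, with 7 false calls. The simulated spreads were drawn from the prior fitted to these data, and that many changed genes ease the adjusted threshold. In the measured data C38D9.2, at a mean log2 ratio of 5.60, had an adjusted p of 0.152 by limma. The recovery can therefore overstate what the test finds here. Alternatives covered the treatment of the dye swap, centring, scaling, quantile normalization, probe choice, filters, the prior, thresholds, the log base, the sign and each array left out. Further alternatives were chosen after seeing the data: zeros kept as a ratio of 1, swapped arrays turned, all probes with 4 ratios, and the sign of the aged ratios turned. The number of arrays limits the precision of every value.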

Results

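The series asked how germline gene expression differed in gonads of C. elegans lacking cde-1, which encodes a terminal uridylyltransferase that adds uridines to small RNAs of the CSR-1 pathway. Gonads of mutant and wildtype worms were compared directly on 4 arrays of 2 colours, 2 from young adults and 2 from aged adults, each stage in both dye orientations. Ratios were present for 11541 and 10775 probes on the young adult arrays with the mutant in Cy5 and in Cy3, and for 12418 and 12704 probes on the aged adult arrays in that order. The SD of the log2 ratios was 0.92 and 0.97 in young adults and 1.40 and 0.86 in aged adults. Genes carrying 10 probes each gave a pooled SD between their probes of 0.20, 0.40, 0.59 and 0.45 log2 units on these arrays. No named probe represented cde-1 itself, so its own level was not analysed here.

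The first comparison was mutant against wildtype over both stages. Ratios are given in the likely direction of mutant over wildtype; if the sign were turned, every higher value would be a lower one, and if no array had been turned before deposit, the averages would hold the dye effect. The gene with the highest ratio was C38D9.2, on chromosome V, at a mean log2 ratio of 5.60 ± 0.52 (limma SE, n = 2 stages), a 48.4-fold ratio. Each ± value is limma's SE, whose variance is drawn toward a value common to all genes. It therefore understates the spread where the stages of a gene disagree widely, and overstates it where they are close. C38D9.2 had the lowest adjusted p. This gene stood at 5.18 in young and 6.01 in aged adults and was positive on all 4 arrays. F15D4.5 on chromosome II followed at 4.57 ± 0.55 and C55C3.3 on chromosome IV at 3.99 ± 0.50, also positive on all 4 arrays. On the low side, cror-1 on chromosome II had a mean of -2.31 ± 0.76 and C18D11.6 on chromosome III a mean of -2.198 ± 0.54, both negative on all 4 arrays. None of these passed the planned test.

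Over the 2222 genes, limma called 0 genes higher and 0 lower at an adjusted p under 0.05. The lowest adjusted p was 0.152, for C38D9.2. An unadjusted p under 0.05 was reached by 72 genes, 61 higher and 11 lower, where chance alone gives 111. With all 4 arrays fitted and stage as a block, 3 genes passed, all higher, each with an adjusted p of 0.048 by limma: C38D9.2, C55C3.3 and Y59E9AR.1. The call count moved with the scaling of the arrays: centring each array on its median gave 13 higher genes and 1 lower, and scaling gave 14 and 2. After centring, limma estimated one common variance for all genes, with an SE of 0.65 for each, so that the calls followed the size of the mean alone.

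The remaining high genes were as large in one stage as in the other in some cases and not in others. F07B7.2 had 3.45 in young and 3.48 in aged adults, and Y59E9AR.1 had 3.37 and 3.18, with stage SDs of 0.025 and 0.14. ZK1248.4 had a mean of 3.20 ± 0.52 and ZK1010.5 a mean of 2.64 ± 0.49. Y43F4A.3 had 5.18 in young and 1.59 in aged adults, a stage SD of 2.54, for a mean of 3.39 ± 0.91. For xdh-1, which encodes xanthine dehydrogenase, the mean was 2.77 ± 0.63, and the aged array with the mutant in Cy5 gave 0.16 while the other 3 arrays gave 3.49 to 3.85; that array's value turned negative once arrays were centred. T02H6.9 had a mean of 2.71 ± 0.58, and citk-1, a citron kinase homologue, had 1.95 in young and 3.30 in aged adults. The pseudogene C06C3.5 had a mean of 2.60 ± 0.49. In the main test the adjusted p of the 12 highest genes ran from 0.152 to 1.

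The low genes were smaller in size than the high ones. C40H1.8 had a mean of -1.80 ± 0.64, C06E4.3 of -1.67 ± 0.53 and srlf-34 of -1.64 ± 0.58. F19B10.2 lay near the same value in both stages, at -1.62 in young and -1.49 in aged adults. Y6D1A.2 and F25D1.5 both had means of -1.48, with aged values of -2.25 and -2.33 against young values of -0.72 and -0.64. C48B4.8 had -1.36 and R10H10.7 had -1.29, in each case with -3.65 on the aged array with the mutant in Cy5 and values nearer 0 on the others; without that array their means were -0.46 and -0.48. C38D4.7 had a mean of -1.26 ± 0.49 and C45B2.2, on the X chromosome, of -1.18 ± 0.49. All 12 had an adjusted p of 1 by limma.

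**Figure D1:**
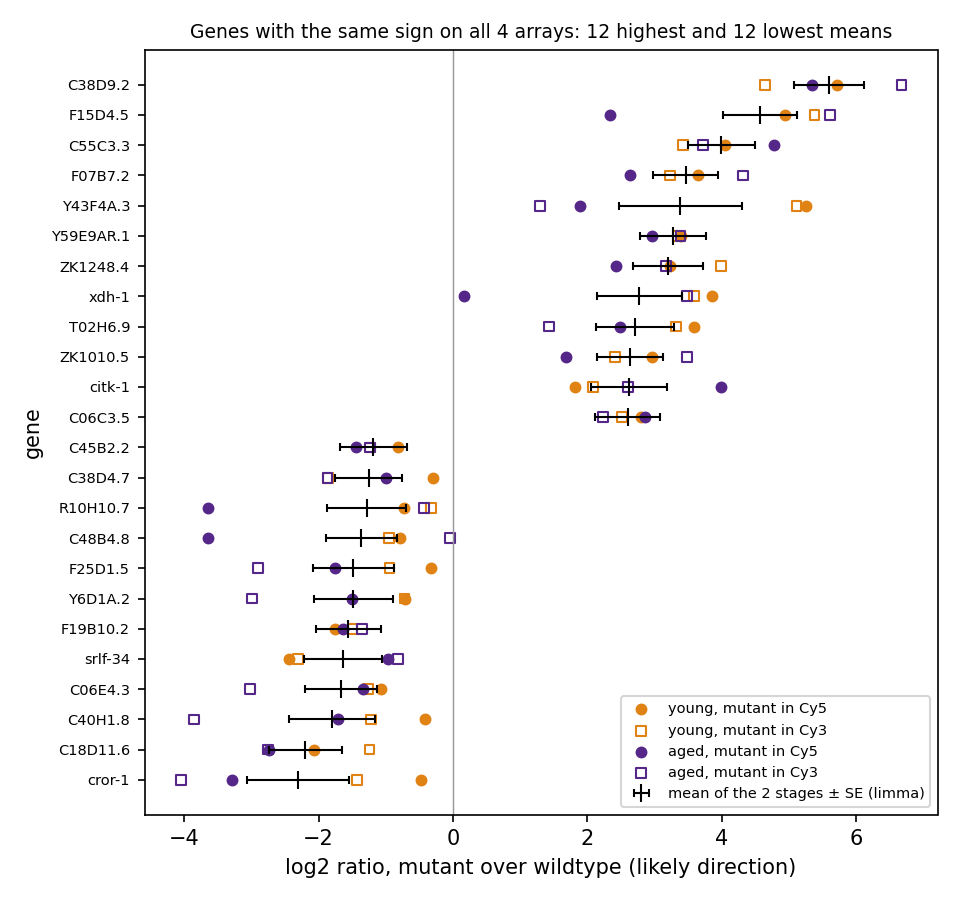
Log2 ratio (x axis, mutant over wildtype in the likely direction) of the 12 highest and 12 lowest genes with the same sign on all 4 arrays (y axis). Filled circles are arrays with the mutant in Cy5 and open squares arrays with the mutant in Cy3, orange for young and purple for aged adults; bars are the mean of the 2 stages with its limma SE. C38D9.2 lies above 4 on every array, and xdh-1 has 1 array near 0.

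X-linked genes formed the only list large enough to test. Their median log2 ratio over both stages was 0.13, against 0.071 for autosomal genes. Of the 248 X-linked genes, 5 had an unadjusted p under 0.05 and 0 passed after adjustment, over all genes tested or adjusted over the list alone. The largest mean ratios in the list were 2.09 ± 0.50 for F23A7.4, -1.70 ± 0.81 for C09B8.4, 1.51 ± 0.49 for F22H10.2 and 1.51 ± 0.55 for F09E10.1. The value of C09B8.4 rested on the aged array with the mutant in Cy3, at -5.38, without which its mean was -0.61; without the other aged array it was -2.78. The list did not stand apart from the other genes by camera (p = 0.672, and p = 0.587 with an estimated correlation). The X-linked median lay 0.12 above the autosomal one in young adults, at the 98.2 percentile of random lists, and -0.0077 from it in aged adults, at the 44.3 percentile. Without the young adult array that had the mutant in Cy5 the difference over both stages was -0.019, and without the aged adult one it was -0.034. From the intracellular pathogen response list only pals-22, a repressor of that response, was tested, with a log2 ratio of 0.20 ± 0.56, and with 0.83 in young and -0.43 in aged adults.

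The second comparison set the stages against each other, since the design treats them as near duplicates. Opposed signs were more frequent than shared ones. Both arrays of one stage were positive and both of the other negative for 729 genes (32.8%, where stages with unrelated signs give 23.5%), of which 425 were negative in young and positive in aged adults and 304 the other way. All 4 arrays had the same sign for 357 genes, where stages with unrelated signs give 526, or 23.7%, from each stage's own counts; 243 of the 357 were positive and 114 negative. ZK616.5 had -2.45 in young and 2.65 in aged adults, and C33G8.2 had 1.68 and -3.22.

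Across the 2222 genes, the young and aged mean ratios had a Pearson correlation of -0.13 and a Spearman correlation of -0.24. Over all 8323 probes with 4 ratios these were -0.23 and -0.32. Without the aged array that had the mutant in Cy5 the Pearson correlation was -0.078, and without the young array that had it in Cy3 -0.084. The orientations within a stage correlated at 0.65 in young and 0.44 in aged adults, while the 4 pairs of arrays from different stages gave -0.047, -0.10, -0.20 and -0.039. The genes are not independent replicates, so no p-value is attached. If no array was turned before deposit, the genotype effect is the difference between orientations, and its stage correlation was positive, at 0.25 (Pearson). The 2 stages' array values did not overlap for 1350 genes (60.8%), where 4 interchangeable values give 33.3%; the 2 arrays of a stage share their RNA, so this excess does not separate age from differences between single RNA samples. Centring shifted aged stage means by a median of 0.18 and young ones by 0.019. After it, 722 genes had opposed stages, 363 of them positive in young adults.

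Large ratios were present in each stage taken alone. In young adults, both orientations exceeded 1 log2 unit for 176 genes and lay below -1 for 112, while 16 genes had orientations beyond 1 unit in opposite directions. In aged adults 214 genes were beyond 1 unit in both orientations with one sign, 57 of them below -1, and 34 had opposite orientations. After centring, 126 genes were above 1 and 82 below -1 in aged adults, and 167 and 123 in young adults. A total of 26 genes were above 1 in both stages, where 12.4 would be shared by independent lists. Another 27 were below -1 in young and above 1 in aged adults (7.91 by chance), and 16 were above in young and below in aged adults (4.51 by chance). For genes below -1 in both stages the count was 3, against 2.87 by chance.

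**Figure D2:**
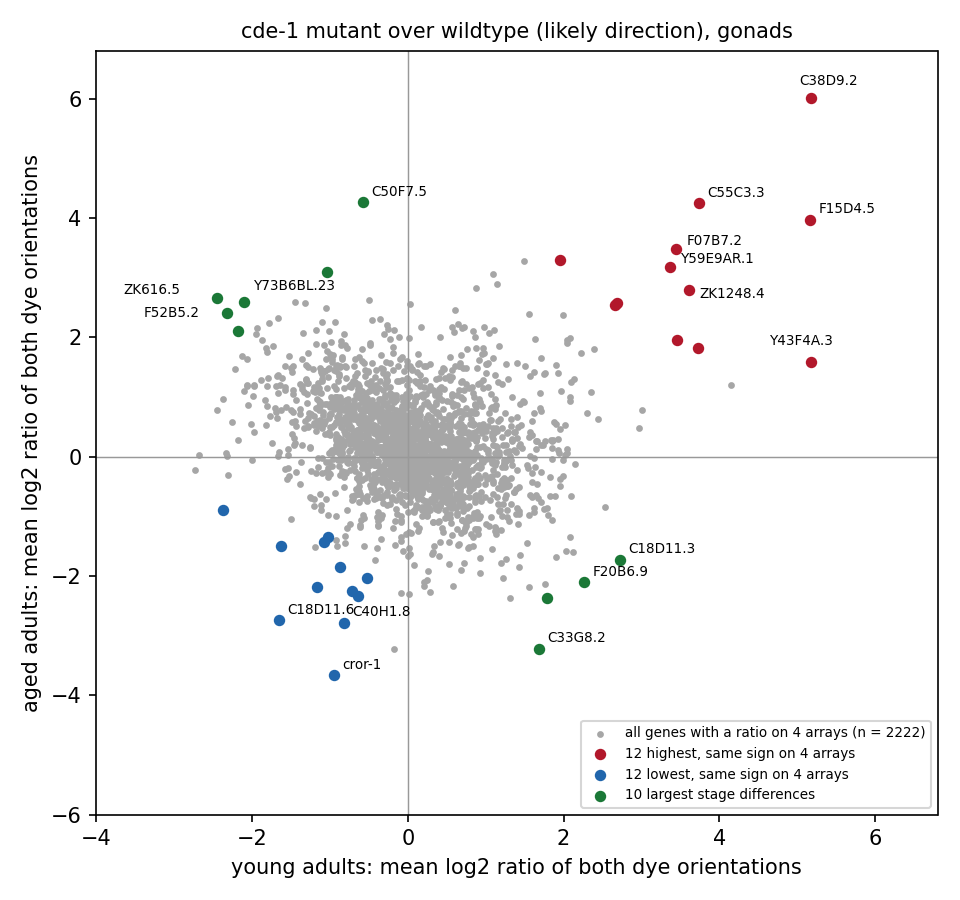
Mean log2 ratio of both dye orientations in young adults (x axis) against aged adults (y axis), mutant over wildtype in the likely direction, for 2222 genes in grey. Red and blue points are the 12 highest and 12 lowest genes with the same sign on all 4 arrays, and green points the 10 largest stage differences; the cloud slopes downward (Pearson -0.13), while the red genes lie in the upper right.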

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

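Of the tests here, those for exchanged labels and for dye bias were chosen only after the result was seen. The 10 genes with the largest stage differences had ratios of one sign on both young arrays and of the other sign on both aged arrays; the differences were not tested, since each stage had 1 RNA sample per genotype. Young minus aged log2 ratios were negative for ZK616.5 (-5.10), C50F7.5 (-4.85), F52B5.2 (-4.73), Y73B6BL.23 (-4.69), F12F6.1 (-4.28) and C48B6.9 (-4.13). They were positive for C33G8.2 (4.90), C18D11.3 (4.45), F20B6.9 (4.37) and the noncoding gene Y9D1A.1 (4.16). After centring, 9 of the 10 stayed opposed, the exception being C50F7.5, whose young array with the mutant in Cy3 lay at -0.072.

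These genes are the extreme of a wider pattern, in which young and aged ratios oppose each other across genes. If no array had been turned before deposit, these averages would be dye effects. The averages correlated at -0.13 (95% interval -0.171 to -0.0892), which goes against that reading if a gene's dye effect is shared by the stages. The orientation differences correlated at 0.25. Shared dye effects would give this if 1 array was turned, and a shared genotype effect if none was, so the reading stays open. Among the 613 genes whose orientations differed by under 0.5 log2 units in both stages, the correlation was -0.205 (95% interval -0.28 to -0.128, with both intervals treating genes as independent). Disagreement between the orientations thus does not account for it in those genes. Over all genes the correlation was -0.078 without the aged array with the mutant in Cy5 and -0.084 without the young array with it in Cy3. The 2 arrays of a stage share their cDNAs, so noise of the single RNA samples stays untested. An exchange of the genotype labels in one stage stays open. Of the 8 genes beyond 2 log2 units on all 4 arrays, 7 had the same sign in both stages (87.5%, exact binomial p = 0.0703, two-sided). A second run over all probes, those of the named genes included, was made after the first had not decided. It gave 25 of 32 (78.1%, exact binomial p = 0.0021, two-sided). Both tests treat genes or probes as independent, unnamed probes can repeat a gene, and the most extreme probes alone exclude nothing. A different tissue makeup of the dissected gonads cannot be told apart from the genotype effect either, because the X-linked shift was -0.0077 in aged adults, within the range of random lists, and a real difference with age stays untested.

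Another pattern is the group of 12 genes with high ratios in both stages, led by C38D9.2, F15D4.5 and C55C3.3. Dye bias stays open for this group. The 12 genes highest in both stages on the arrays with the mutant in Cy5, 8 of them in this group, were all positive on the other orientation, with a median of 2.87. That goes against dye bias only if 1 orientation was turned before deposit, since an unturned dye effect would give the same. The negative correlation of the averages over all genes does not settle this for genes chosen as high in both stages. A single noisy array is argued against because 11 of the 12 genes kept a mean above 2 log2 units whichever array was left out; xdh-1 went down to 1.94. A difference between the strains, at cde-1 or at other loci, also stays open. Matching of related genes to one probe was not tested, since probe sequences were not used here.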

How the results depend on the processing

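Zeros kept, swapped arrays turned, all probes and aged sign turned were chosen after seeing the data. The 0 calls moved most. Higher counts were 3 with stage as a block, 13 after centring, 14 after scaling, 14 after quantile normalization, 1 without genes of mean absolute ratio under 0.2 and 61 at an unadjusted p under 0.05. Leaving out 1 array gave 9 to 16, the lone orientation being assumed to vary like the averages. Lower counts were 1 after centring, 2 after scaling and 11 unadjusted, and 0 to 4 leaving out 1 array. All 12 highest genes and 1 of the 12 lowest were among the calls after centring. limma's prior degrees of freedom rose from 4.47 to infinity after centring, scaling, quantile normalization or leaving out any array but the first aged one (79), so the count rests on how the spread of 2 stages is pooled. The robust prior, a dye term, probe level and an adjusted p under 0.1 gave 0 calls.

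The stage correlation of -0.13 was -0.21 without genes whose orientations differed by over 1, -0.23 over all probes, -0.086 with zeros kept, -0.078 to -0.15 leaving out 1 array, and 0.13 with the aged sign turned, by construction. It was 0.25 with swapped arrays turned, the reading in which no array was turned before deposit. Among 8323 probes, 5162 separated the stages. Orientation agreement was 0.87 in young and 0.82 in aged adults without genes differing by over 1, which that filter produces, and 0.42 and 0.24 with zeros kept. Leaving out 1 array gave X-linked differences of -0.034 to 0.17 and pals-22 ratios of -0.15 to 0.55; the cause was not tested. Of 736 values of named genes under 26 settings, 589 kept direction and call, 114 passed the threshold of their setting, 32 moved by more than their spread and 1 reversed. The 589 do not measure stability. Several settings, such as the robust prior, cannot change a gene's ratio, and not passing was already the main call. The 114 include values at an unadjusted p under 0.05 and values from fits with infinite prior degrees of freedom. No paired analysis was possible because the labels give no replicate numbers that link samples, and each ratio already sets mutant beside wildtype. Signal over background was not used here, so which ratios are dim is unknown.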

Other observations

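Only the test of neighbouring genes on the mean of both stages was planned before its result was seen. The gene families below were picked after seeing the data, by name stem. As an exception, pigc-1, pigm-1 and similar genes were joined into a pig family, though their stems differ by a letter. Setting family medians against random lists is therefore no independent test. Families of 4 or more tested genes numbered 23, and 4 of them in young and 2 in aged adults had medians outside the central 95% of random lists, where chance gives 1.15 in each. The 4 include the joined pig family. All 6 spig genes had ratios of 1.34 to 2.08 in young adults (median 1.89), with an aged median of 0.42. The 7 nspg genes, nematode-specific peptides, had a young median of 1.57 and an aged median of 0.035, which turned to -0.14 after centring. The 10 lido genes had medians of 0.61 in young and 1.37 in aged adults, with lido-15 at 2.46 and lido-9 at 2.22 in aged adults.

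A median below 0 in young and above 0 in aged adults was found for 10 of the 23 families as deposited and for 7 after centring, and the reverse for 3 and 4. Among the 10, the young median lay outside the central 95% of random lists in 2 and the aged median in 0. The 6 eif genes, grouped by a name taken from translation initiation factors, had medians of -0.83 in young (0.71 percentile of random lists) and 0.81 in aged adults (95.2 percentile). Of these, 5 had opposite stage means but 2 were opposed on all 4 arrays, and 3 were negative on the aged array with the mutant in Cy3. The 7 pig genes, grouped by a name taken from GPI anchor biosynthesis, had medians of -0.89 (0.58 percentile) and 0.79 (95 percentile), with 6 opposite in their stage means and 5 on all 4 arrays. Both families kept the signs of their medians after centring, scaling and quantile normalization. The 6 cest genes had an aged median of -0.64.

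Neighbouring genes had similar ratios. Over 347 adjacent pairs of tested genes, the mean ratios correlated at r = 0.253, with 10000 shuffles giving a one-sided permutation p of 2e-04 (0.000667 after adjustment over 5 such tests). Without genes beyond 2 log2 units it was 0.22 over 342 pairs (permutation p = 4e-04, from shuffles that still drew on all genes). In young adults it was 0.19 (permutation p = 3e-04) and in aged adults 0.14 (p = 0.0049), all one-sided. For the young minus aged difference r was 0.092, with a one-sided permutation p of 0.046 before and after adjustment, though r lay within the central 95% of shuffles (-0.107 to 0.105). Of the 9 pairs that include a gene named by the rule, 5 had the same sign, such as F07B7.2 at 3.46 and F07B7.1 at 0.92, and 4 had opposite signs, such as C45B2.2 at -1.18 and spig-20 at 1.22. What underlies this was not tested, related genes in tandem that share a probe's target included.

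Of 6013 probes without a gene name here and with 4 ratios, 17 (0.283%) lay above 2 log2 units on all 4 arrays, a share close to that of the named probes, 7 of 2310 (0.303%). Below -2 lay 1 unnamed and 0 named probes. Another 5 unnamed probes were beyond 2 log2 units with the stages opposed.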
